A study of Mus musculus with 6 samples.

How the data were processed

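RNA-seq libraries were made from pancreatic macrophages of mice, 1 library per day from pools of more than 3 mice: mock (day 0) and days 1, 3, 4, 5 and 7 after caerulein. Per the labels' protocols and the design text, leukocytes were enriched with magnetic beads, macrophages were sorted by flow cytometry and lysed in Trizol, and libraries were made with an Illumina RNA library kit. The groups were taken from the sample titles.

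The deposited values are a normalised signal per gene, as deposited by the authors, for 31617 genes in 6 libraries. Each deposited column holds whole multiples of 1 step, so the authors' values are gene counts divided by 1 factor per library. In every library 100% of values came out whole within a tolerance of 0.01 reads. The factors recovered this way equal median-of-ratios size factors over all genes with reads in every library. Centring on the median expressed gene, an alternative below, uses the 10000 expressed genes with the pseudocount instead and so differs. Bowtie 0.12.2 and the genome build mm8 are named in the submitters' processing notes, without a role. The gene counter and annotation are not given in the sources used here. Because the gene identifiers could not be tied to that build, no coordinates are given. Of the identifiers, 31431 (99.4%) were found in a table of mouse gene names, and gene names were used as deposited. Whether counting used strand or how it treated reads shared by near-identical genes is not given in the sources used here, so values of paralogs, such as the Reg family, trypsinogens, haemoglobins and Ly6c1 and Ly6c2, are uncertain.

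Reads per library were 17598031 for mock and 16200131, 25726455, 14853084, 17905449 and 16358551 for days 1, 3, 4, 5 and 7. A floor of 3 reads was worth between 2.11 and 3.88 normalised units. For named genes a 95% Clopper-Pearson interval of the ratio of reads was computed. On the log2 scale it reached 0.24 to either side of its middle at the median over the comparisons that named 79 leading genes. A gene named in several comparisons entered once for each. The widest interval reached 3.90, for Csf3. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and say nothing of the variation between pools of mice.

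Before the data were examined, the groups, comparisons, gene lists, naming rule and a set of alternatives were fixed. Expressed genes were the 10000 with the highest mean over the 6 libraries, the lowest of which had a mean of 74.1. Log2 ratios used a pseudocount of 17.8, set from the mean column total, which understates the ratios of low genes. Genes were counted at 2-fold, and for the day of the highest and lowest value at a range of 4-fold. Pearson correlations and principal components used the same log2 values. With 1 library per day a pair of days cannot be tested against each other, and no p-value across genes was computed for the ratios.

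There were 40 gene lists, 20 for macrophage states, 4 for RNA quality and handling and mouse sex, and 16 for other cells. A list's median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, and lists with fewer than 3 expressed members were given as values. Lists share some members, such as Spp1, Timd4 and Krt19. Several markers of other cells, such as Kdr, Klrk1 and Cd22, were also abundant where the other members of their list were not. The named genes are, for each day against mock, the 8 highest and 8 lowest, for each step between days the 4 highest and 4 lowest, up to 4 members of each list with the largest ratio, and the 3 genes of the sort. Predicted genes, small RNAs, pseudogenes and immunoglobulin and T cell receptor segments were left out of the first 2 parts. Some genes that the rule names are not reported here. The pattern for small RNA names beginning with Rn was narrowed to Rn with a digit after the data were seen, which left the named genes as they were.

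Because whole reads were recovered, count tests on them were added after the data were seen. They used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 in R 4.3.3, on 14106 genes with at least 60 reads over the 6 libraries, for the 5 caerulein libraries against mock and for a linear trend over day. The trend took mock as day 0, and both tests treat libraries of different days as replicates. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

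The calculations were tested on simulated data with the real means and depths. For day 1 against mock over 10000 genes, with no variation between libraries, 98.0% of genes changed by 1.5 on the log2 scale passed 2-fold, and with a coefficient of variation of 0.3 it was 77.6%, while 984 of 9791 unchanged genes passed as well. Of 200 unchanged lists of 15 genes, 4 passed the limits with a coefficient of variation of 0.3 and 7 with none. In the test of 5 libraries against mock over 14108 genes, with a coefficient of variation of 0.3, edgeR called 198 of 200 genes changed 8-fold and 7 unchanged genes. On the real reads edgeR's common coefficient of variation was 0.50.

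Alternatives were a pseudocount of 1.78 or of 5 times the main one, the 6000 highest genes or no filter, centring each library on its median expressed gene or quantile normalisation, leaving out acinar, erythroid and mitochondrial genes with rescaling to equal totals, unmatched random lists and list means. Chosen after the data were seen were leaving out 438 genes that move with markers of other cells (correlation above 0.9 with an acinar, fibroblast, T, NK or B cell list, and all members of other-cell lists), leaving out the mock, day 3 or day 7 library from the day of highest and lowest value, and the count tests.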

Results

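RNA was sequenced from macrophages sorted from the pancreas of wild-type Balb/c mice as CD45+CD11b+F4/80+ cells, that is, leukocytes carrying the myeloid integrin CD11b and the macrophage protein F4/80. Acute pancreatitis was induced with 10 hourly injections of caerulein, a cholecystokinin analogue that overstimulates the acinar cells, and macrophages were taken on days 1, 3, 4, 5 and 7 after the first injection. Day 4 is given by the labels of its sample, while the design text names the other days alone. Saline-injected mock mice served as day 0. There was 1 library per day, pooled from more than 3 mice, so no difference between days has a replicate check. The libraries held 17598031 reads for mock and 16200131, 25726455, 14853084, 17905449 and 16358551 for days 1, 3, 4, 5 and 7. The comparisons ask how the macrophage transcriptome differed from mock on each day and between successive days. Log2 ratios below are between normalised read counts with a pseudocount, and a list of genes is said to stand above or below other genes when its median ratio lay at or beyond the 99th or 1st percentile of 10000 random lists matched on mean expression. This describes these libraries, not the conditions.

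The genes that define the sort were present on every day. Ptprc, which encodes CD45, had a normalised read count of 11870 in mock and of 12626, 7282, 9425, 11351 and 11553 on days 1, 3, 4, 5 and 7. Adgre1, which encodes F4/80, had 11750 in mock and 10592, 12632, 11541, 23702 and 9671 on those days. Itgam, which encodes CD11b, had 1900 in mock, 2627 on day 1, 1409 on day 3, 678 on day 4, 687 on day 5 and 1097 on day 7. The 3 genes as a list stood within the random lists on all 5 days, with medians between -0.43 and 0.09, of which those of days 1, 5 and 7 changed sign with scaling.

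On day 1 the library was rich in interferon-induced and monocyte transcripts and poor in transcripts of resident macrophages, antigen presentation and division. Of 28 interferon-induced genes 23 were at least 2-fold higher than in mock and 0 at least 2-fold lower, with a median log2 ratio of 1.92. Among them Ifit2 was at 2.76, Isg15 at 2.74, Irf7 at 2.72 and Rsad2 at 2.69. Of 12 monocyte genes 7 were higher and 2 lower (median 1.72), led by Ly6c2 at 3.79, the surface marker of inflammatory monocytes, and Thbs1 at 3.27. Chemokines that attract monocytes were also higher, Ccl12 by 2.56, Ccl7 by 2.30 and Ccl2 by 2.17, although the chemokine list as a whole stood within the random lists (median 0.15, below 0 under another scaling, at -0.23). Lower were 9 of 14 genes of resident macrophages (median -1.56), with the hyaluronan receptor Lyve1 at -3.01 and the phosphatidylserine receptor Timd4 at -2.97. MHC class II genes had 11 of 12 members lower (median -2.39), with H2-Aa at -2.66, its chaperone Cd74 at -2.58 and the class II transactivator Ciita at -2.51. B cell genes, with 11 of 12 lower (median -1.65), and dendritic cell genes (median -0.85) stood below others with them.

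Genes of S phase and mitosis were lower on day 1 in 27 of 30 cases (median -2.33), with Birc5 at -3.46 and Ccnb2 at -3.41. Erythroid (median -3.42), T cell (-2.05), fibroblast (-1.86) and NK cell genes (-1.39) and mRNAs of the mitochondrial genome (-0.98) stood below others with them. Alternative activation genes stood below others (median -1.12), though the members parted: the lipoxygenase Alox15 (ENSMUSG00000018924) was at -5.39, with a 95% counting interval of -6.06 to -5.32 for the ratio without pseudocount, and Mgl2 at -3.83, while the chitinase-like Chil3 was at 2.43. Genes of the unfolded protein response stood above others (median 0.82), with Creld2 at 1.71 and Ddit3 at 1.57, and so did matrix remodelling genes (median 0.78), with Spp1, which encodes osteopontin, at 3.81. Lipid and lysosome genes stood above others (median 1.19), led by Spp1, Gpnmb at 3.79 and Fabp5 at 3.41. Below others stood complement genes (median -1.22), growth factor genes (median -0.70), with Hbegf at -2.79, classical activation genes (median -0.73), with Il1a at -3.96 and Il6 at -2.69, and genes for uptake of dead cells (median -0.19). Matrix, growth factor, complement and uptake genes came within the random lists under at least 1 alternative. The highest ratios of all named genes were those of the endothelial lipase gene Lipg (ENSMUSG00000053846, 4.98), the transcription factor gene Pou3f1 (4.20), Pcp4l1 (4.14), Cdo1 (4.06) and the serotonin receptor gene Htr2b (3.97). The lowest after Alox15 were Retnlg (-4.26), Reg3d (-4.15), Ctsf (-4.11), Hpgd (-4.08), Reg3a (-4.07), Clps (-4.04) and Gpr34 (-4.03).

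In all, 668 of the 10000 expressed genes were at least 2-fold higher and 958 at least 2-fold lower on day 1 than in mock. In libraries simulated for this comparison with a coefficient of variation of 0.3 between libraries, 984 of 9791 unchanged genes also passed 2-fold in either direction. The observed shares of expressed genes past 2-fold against mock were 16.3%, 9.4%, 11.4%, 10.1% and 8.5% on days 1, 3, 4, 5 and 7. Variation between pools was not measured, so such counts alone do not separate treatment from it. The split was 488 to 1126 after centring each library on its median expressed gene and 320 to 1422 with acinar, erythroid and mitochondrial genes left out. Here and on later days that last setting also rescaled libraries to equal totals in place of the authors' factors. Neither step was run alone, so its splits cannot be put down to the genes left out.

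**Figure D1:**
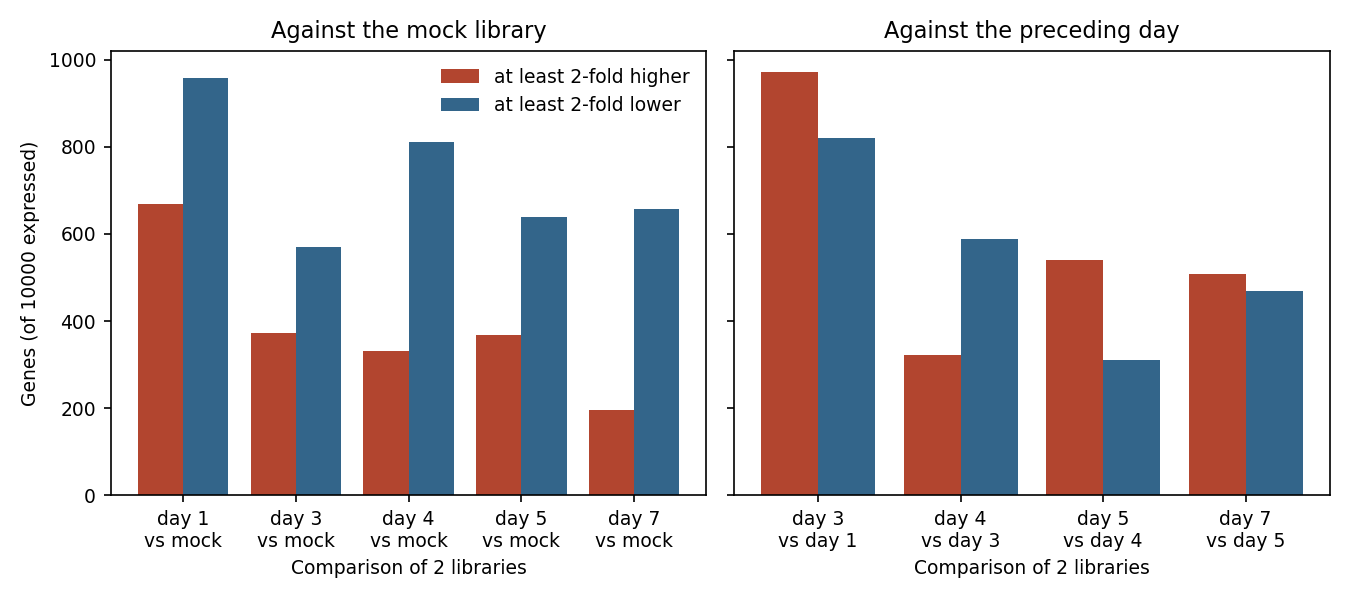
Number of the 10000 expressed genes at least 2-fold higher (red) or at least 2-fold lower (blue) in 1 library than in another, on the left for each day against mock and on the right for each day against the day sampled before. The highest bar is the 972 genes higher on day 3 than on day 1, and the lowest the 196 genes higher on day 7 than in mock.

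On day 3 the interferon-induced genes were low and the genes of dividing cells high. Of the 28 interferon-induced genes 26 were at least 2-fold lower than in mock (median -2.04), with Ifit2 at -3.42 and Ifit3 at -3.17. Between day 1 and day 3 all 28 were lower (median -3.72), and Ifit2 differed by -6.18. Cell-cycle genes were higher than mock in 24 of 30 cases (median 1.53), with the cyclin gene Ccnb1 at 2.21, Cdk1 at 2.04 and Birc5 at 1.92, and higher than on day 1 in 29 of 30 (median 3.83). Ribosomal protein genes stood above others on day 3 against mock (median 0.64) and against day 1 (0.60), as did mRNAs of the mitochondrial genome against day 1 (0.96). Monocyte genes stood below others (median -0.66), with Ly6c2 at -3.42 against mock and -7.21 against day 1. MHC class II genes were still lower than mock in 9 of 12 cases (median -1.68), beside B cell genes with 11 of 12 lower (median -2.52) and dendritic cell genes (median -0.39). Lipid and lysosome genes again stood above others (median 1.24), with Spp1 (ENSMUSG00000029304) at 4.32, Gpnmb at 3.64 and the lysosomal protease gene Ctsd at 2.61. Resident macrophage genes (median -0.47), alternative activation genes (-0.68), classical activation genes (-0.29) and chemokines (-0.44) stood below others, the last with Cxcl13 at -3.35. Classical activation genes were within the random lists among the 6000 highest genes.

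Transcripts of collagen-producing and duct cells were also higher in the day 3 library. Of 10 fibroblast and stellate cell genes 8 were at least 2-fold higher than in mock (median 2.30), with Col1a1 at 3.65 and Postn at 3.35, and of 5 duct cell genes 4 were higher (median 2.54), with Krt19 at 3.45. The 3 haemoglobin genes of the erythroid list had a median of 1.06, above others but not with quantile normalisation. Other leading genes on day 3 were Htr2b (4.79), Clu (4.06) and Syngr1 (3.99) on the high side, and Retnla (-5.07), Lars2 (-4.98), Cd79a (-4.88), Pnlip (-4.55), Fcmr (-4.52), Timd4 (-4.50) and Ngp (-4.36) on the low side. In all, 373 genes were at least 2-fold higher and 571 lower than in mock, and 972 higher and 821 lower than on day 1. With acinar, erythroid and mitochondrial genes left out the splits were 247 to 713 and 1162 to 633. When genes that move with markers of other cells were left out, a choice made after seeing the data, 357 were lower than in mock. Those genes were picked partly by their course over these same libraries, so a lower count was built in.

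**Figure D2:**
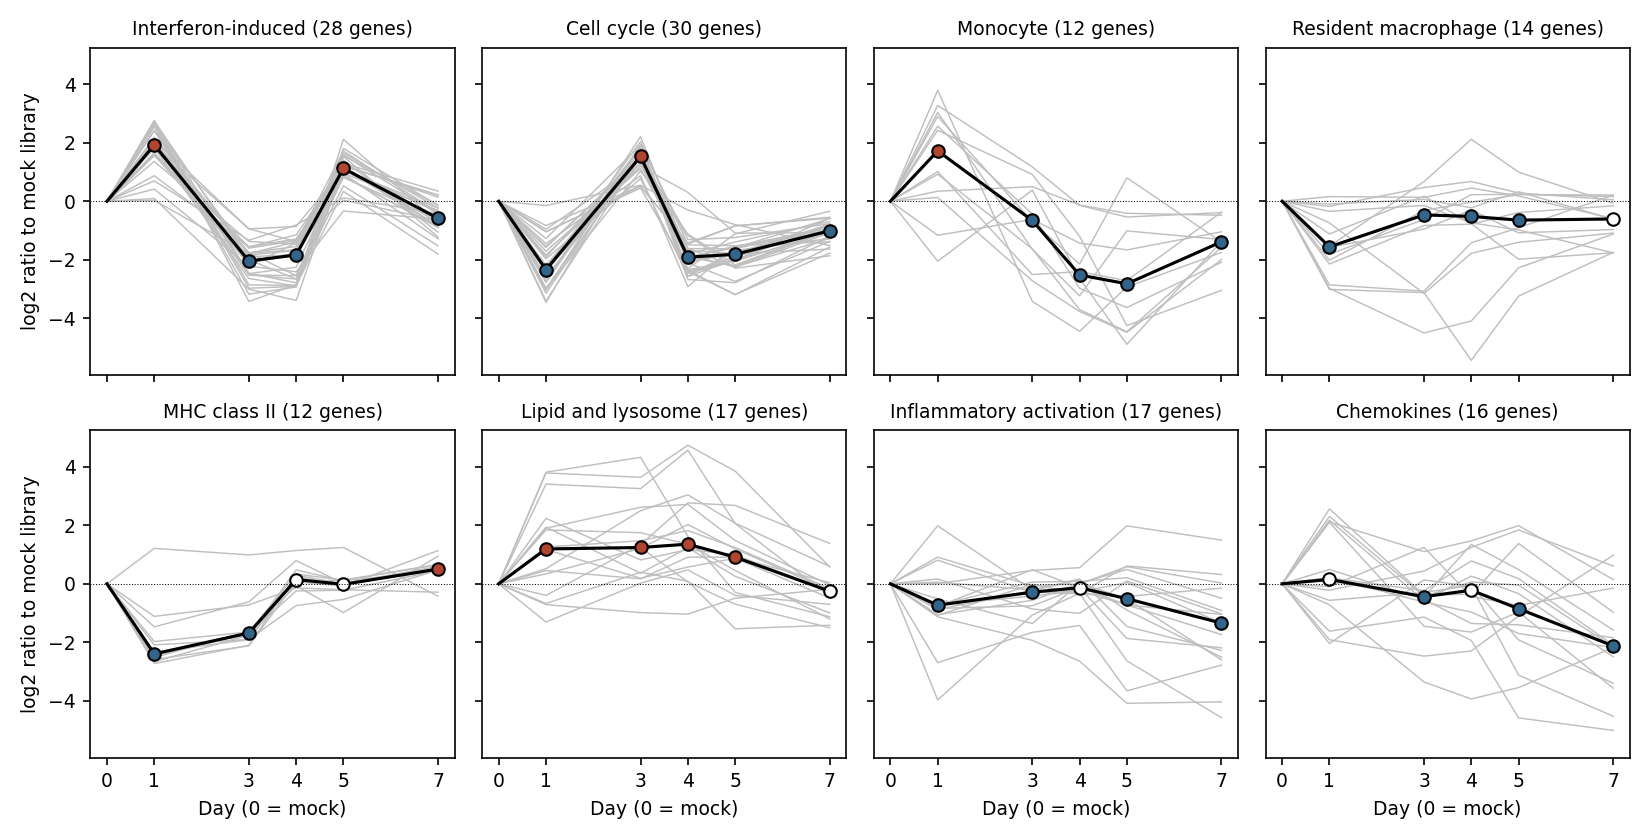
Log2 ratio to the mock library by day for 8 gene lists, with each expressed member as a grey line and the list median as a black line; red points stood above other genes, blue points below and white points within the random lists. The interferon-induced median was 1.92 on day 1, -2.04 on day 3 and 1.12 on day 5, and the cell-cycle median was above 0 on day 3 alone, at 1.53.

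On day 4 genes of lipid-loaded macrophages had their highest median and MHC class II genes were back near the mock level. Lipid and lysosome genes had 11 of 17 members at least 2-fold higher than in mock (median 1.35), with Gpnmb (ENSMUSG00000029816) at 4.73, the fatty acid binding protein gene Fabp5 at 4.56, the lipid receptor gene Trem2 at 3.04 and Apoe at 2.76. MHC class II genes were higher than on day 3 in 10 of 12 cases (median 1.63), with H2-Aa at 2.23 and Cd74 at 2.19. Genes of other cells that carry MHC class II also stood above others in this step, dendritic cell genes with a median of 0.94 and B cell genes with 0.52, and so did immediate early and heat shock genes, with 9 of 19 higher (median 0.77). The median of the MHC class II genes against mock was 0.15, and -0.13 at the lowest under another scaling. Cell-cycle genes were lower than on day 3 in 28 of 30 cases (median -3.42), with Ccna2 at -4.33, and lower than mock in 28 (median -1.91). Interferon-induced genes stayed low (26 of 28 lower, median -1.83). Monocyte genes were lower than mock in 10 of 12 cases (median -2.52), with Ly6c2 at -4.44. Resident macrophage genes stood below others (median -0.52) with members apart: Lyve1 was at -5.43 and Timd4 at -4.09, but the selenoprotein P gene, listed as Sepp1, at 2.12. Glycolysis genes (median -0.97, Pkm -1.53) and unfolded protein genes (median -0.70, Sdf2l1 -1.11) stood below others, and macrophage core genes above (median 0.43, Mpeg1 1.28). As means, unfolded protein and macrophage core genes were within the random lists.

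Collagen genes were lower on day 4 than on day 3, Col1a1 by -5.55 with a 95% counting interval of -6.71 to -5.58 for the ratio without pseudocount. The fibroblast list median was -3.48 against day 3 and that of duct cell genes -2.34. Further leading genes against mock were Syngr1 (4.63), Htr2b (4.40), Cdo1 (3.77), Rapsn (3.48), Ms4a7 (3.23) and the metalloproteinase gene Mmp27 (3.08), and on the low side the pancreatic lipase gene Pnlip (ENSMUSG00000046008, -6.00), Cela1 (-5.09), Cel (-4.87), Gp2 (-4.86), Sycn (-4.75), Ly6c1 (-4.61) and Ctrc (-4.58), most of them genes of acinar digestive enzymes. Against day 3 the arginase gene Arg1 was at -4.56, whereas Lars2 was at 5.75, Pla2g2d at 3.96 and Retnla at 3.62. In all, 331 genes were at least 2-fold higher and 811 lower than in mock, and 323 higher and 589 lower than on day 3. Against mock the split was 466 to 719 with quantile normalisation and 170 to 1166 with acinar, erythroid and mitochondrial genes left out, and against day 3 it was 416 to 487 with quantile normalisation.

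On day 5 interferon-induced genes were high again, in the library taken 1 day later. Of 28 genes 27 were at least 2-fold higher than on day 4 (median 3.16), with Ifit2 at 4.96, Iigp1 at 4.62 and Irf7 at 4.59, and 18 were higher than in mock (median 1.12). NK cell genes were higher than on day 4 in 7 of 7 cases (median 1.70) and fibroblast genes in 5 of 10 (median 1.08), while mRNAs of the mitochondrial genome (median -1.17) and ribosomal protein genes (-0.57) stood below others in this step. Macrophage core genes had their highest median against mock (0.92), with Mpeg1 at 1.74 and the apoptotic cell receptor gene Mertk at 1.27. Lipid and lysosome genes stood above others (median 0.91), though they were lower than on day 4 (median -0.87, Fabp5 -2.51). Growth factor genes, with 6 of 15 higher and 4 lower (median 0.50, Gdf3 1.88), and genes for uptake of dead cells, with 5 of 15 higher and 2 lower (median 0.44, Axl 1.92), stood above others as medians but within the random lists with quantile normalisation and as means (0.15 and 0.36). Monocyte genes had their lowest median, -2.82, with fibronectin gene Fn1 at -4.89 and Chil3 at -4.25, and neutrophil genes theirs, -3.56, with 8 of 9 lower. Classical activation genes stood below others (median -0.51), with Irg1 at -4.08 and Il6 at -3.65, and so did chemokines (median -0.85), with Cxcl3 at -4.58 and Cxcl1 at -3.12. Cell-cycle (median -1.81), resident macrophage (-0.64), alternative activation (-0.46), glycolysis (-0.67), unfolded protein (-0.36) and respiratory chain genes (-0.24) also stood below others, the last 2 not as means.

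The leading named genes on day 5 against mock were Gpnmb (3.85), Syngr1 (3.50), Ms4a7 (3.33), Slc27a1 (2.95), Olfml3 (2.74), Apoe (2.68), Cd22 (2.46) and Ms4a14 (2.43). On the low side they were Gp2 (-5.69), Reg3g (-5.52), Sycn (-5.51), Pnlip (-5.32), Serpinb2 (-5.15), Arg1 (-5.14), Ctrc (-5.12) and Slpi (-5.00). Against day 4 Retnlg was at -5.15 and Reg3b at -3.61. In all, 368 genes were at least 2-fold higher and 640 lower than in mock, and 540 higher and 311 lower than on day 4. Against mock the split was 260 to 728 after centring on the median gene and 187 to 814 with acinar, erythroid and mitochondrial genes left out. Against day 4 the direction of the split depended on scaling, with 384 to 475 after centring on the median gene and 399 to 425 after quantile normalisation.

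On day 7 cytokine and chemokine genes were lower than in the 1 mock library, and genes of acinar, fibroblast and lymphoid cells were at or above the mock level. Of 16 chemokine genes 11 were at least 2-fold lower than in mock (median -2.12), with the neutrophil attractants Cxcl3 at -5.01 and Cxcl1 at -4.52 and with Cxcl10 at -3.56. Of 17 classical activation genes 11 were lower (median -1.34), with Il1a at -4.57, Irg1 at -4.03, Il6 at -2.77 and Tnf at -2.60. Their median was below 0 against mock on every day, at -0.73, -0.29, -0.13 and -0.51 on days 1, 3, 4 and 5. Whether their level in that mock pool was itself high was not tested. Medians of mRNAs of the mitochondrial genome (-1.33), ribosomal protein genes (-0.65) and neutrophil genes (-0.90) were also below 0 against mock on day 7. Csf3, the granulocyte growth factor gene, had 1 read against 258 in mock, a log2 ratio of -8.19 without pseudocount, with a counting interval of -13.5 to -5.70. Lipid and lysosome genes were lower than on day 5 in 11 of 17 cases (median -1.30), with Gpnmb at -3.27, and interferon-induced genes in 23 of 28 (median -1.73). Macrophage core genes were lower in the same step in 12 of 17 cases (median -1.12), while the medians of acinar (4.25), T (1.63), NK (1.85) and B cell genes (2.11) were above 0. MHC class II genes stood above others against mock (median 0.50), with Ciita at 1.14, and so did dendritic cell genes (median 0.65), with 3 of 10 higher and 0 lower. Alternative activation genes had a median of 0.21, but -0.12 among the 6000 highest genes and -0.48 as a mean, with Arg1 at -3.99 and Il10 at -3.40. Monocyte genes (median -1.38), cell-cycle genes (-1.01), interferon-induced genes (-0.58), glycolysis genes (-0.97), unfolded protein genes (-0.98) and matrix remodelling genes (-0.76, Timp1 -2.67) stood below others, the last not among the 6000 highest genes.

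The highest named genes against mock on day 7 were Slc27a3 (2.39), Islr (2.34), the basement membrane gene Nid1 (2.29), the collagen gene Col6a1 (2.28), Mmp2 (2.23), Col6a2 (2.17), the trypsinogen gene Prss1 (2.16) and Mest (2.11). The low side also held Arg1, Il1r2 (-3.96) and Clec4e (-3.96). Against day 5 the highest were Dmbt1 (5.87), Gp2 (5.73), Pnlip (5.23) and Sycn (5.07). In all, 196 genes were at least 2-fold higher and 657 lower than in mock, and 507 higher and 468 lower than on day 5. These splits depended on scaling. Against mock they were 279 to 483 after centring on the median gene and 438 to 514 with quantile normalisation. With acinar, erythroid and mitochondrial genes left out the split was 686 to 260, the setting that turned the direction. That setting also rescaled libraries to equal totals, and neither step was run alone. Which step turned the direction is therefore not known. Against day 5 the splits were 627 to 263, 558 to 317 and 1040 to 119, with more genes higher each time. With genes that move with markers of other cells left out, 250 genes were higher than on day 5. Those genes were picked partly by their course over these same libraries, so a lower count was built in.

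Transcripts of cells outside the sort followed their own course. Acinar genes were at least 2-fold lower than mock in 27 of 27 cases on day 1 (median -3.47), in 23 on day 3 (-2.67), in 27 on day 4 (-3.78) and in 26 on day 5 (-4.06), and had a median of 0.20 on day 7. They took 6.13% of the reads in mock, 0.482%, 1.15%, 0.397% and 0.305% on days 1, 3, 4 and 5 and 8.70% on day 7. Genes of the Reg family, secreted by acinar cells, had medians of -3.37, -0.84, -2.38, -4.63 and -0.63 on days 1, 3, 4, 5 and 7. T cell genes had medians of -2.05, -2.32, -1.54, -1.27 and 0.69 on the same days, NK cell genes of -1.39, -3.62, -2.34, -0.55 and 1.16, and B cell genes of -1.65, -2.52, -2.17, -2.10 and 0.15. Fibroblast and stellate cell genes had medians of -1.86, 2.30, -1.61, -0.49 and 1.52, and duct cell genes of 0.71, 2.54, 0.17, -1.26 and 0.79. Of the duct cell medians the first was -0.27 with no filter on low values and the third was -0.09 at the lowest under another scaling.

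Among other blood cells, neutrophil genes had medians of 0.13, -1.47, -1.67, -3.56 and -0.90 on days 1, 3, 4, 5 and 7, the first below 0 (-0.19) under another scaling. Eosinophil genes had -1.70, -0.60, 0.79, -1.63 and 0.28, dendritic cell genes -0.85, -0.39, 0.51, 0.25 and 0.65, and erythroid genes -3.42, 1.06, -2.03, -4.47 and -0.39. The standing of dendritic cell genes on days 3, 4 and 7, eosinophil genes on day 4, neutrophil genes on day 7 and NK and duct cell genes on day 5 was lost under at least 1 alternative. The 4 expressed endothelial genes stood within the random lists on all 5 days, with Kdr at 3.61 and Plvap at -3.10 on day 1. Of the endocrine, mesothelial and mast cell lists 1 gene each was expressed: on day 3 Gcg was at 1.90, Krt19 at 3.45 and Hdc at -1.70. Of the platelet list 0 genes were. Genes of fatty acid oxidation and of iron and redox handling stood within the random lists on all 5 days, with medians from -0.15 to 0.24 and from -0.53 to 0.14, and both changed sign with scaling on some days.

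**Figure D3:**
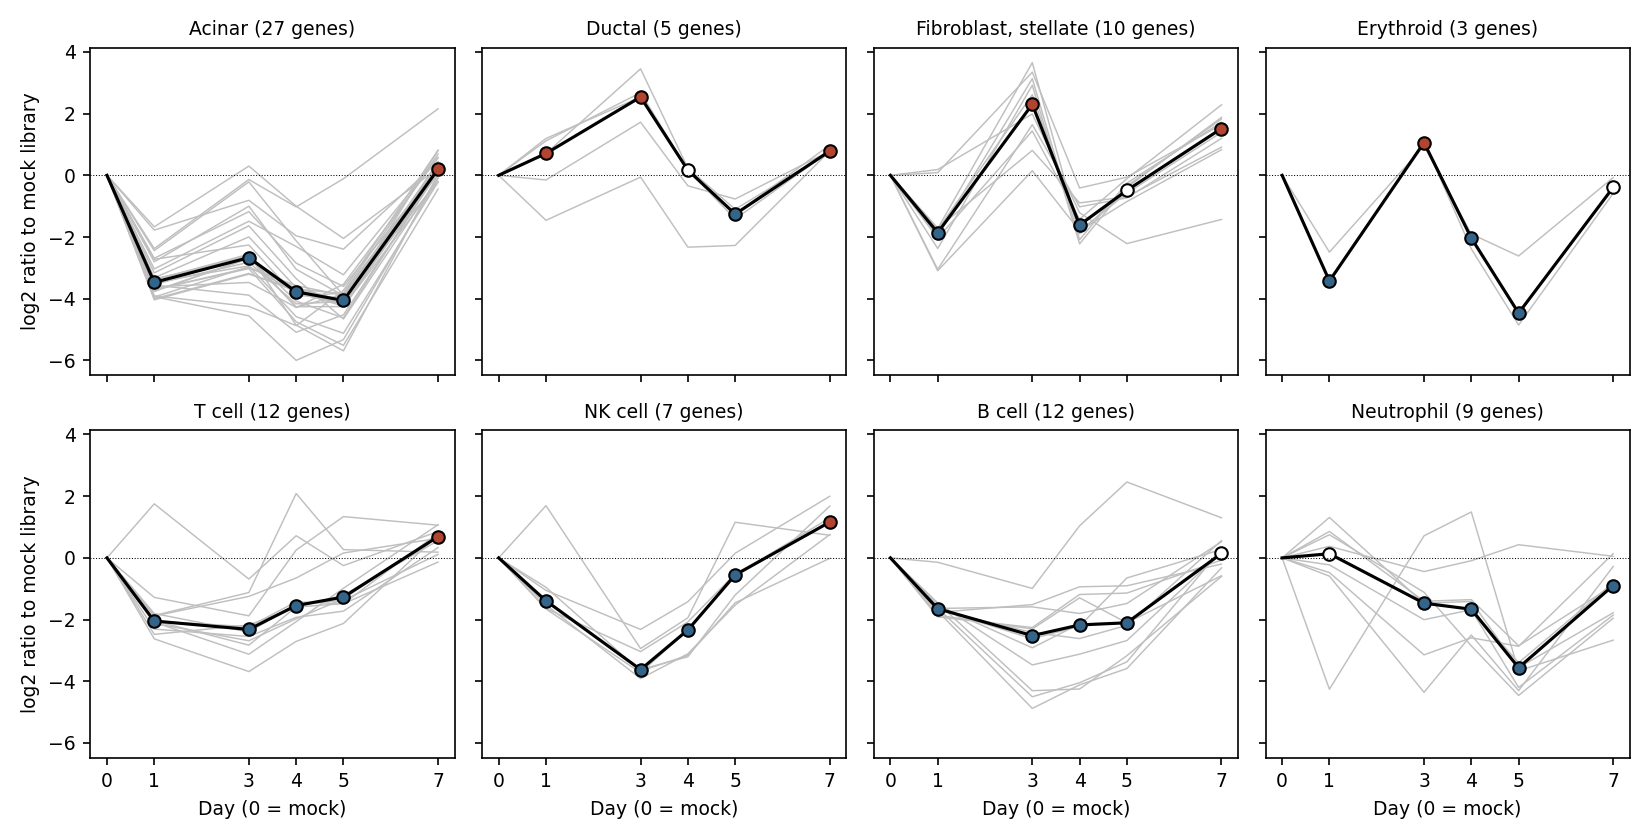
Log2 ratio to the mock library by day for 8 lists of markers of other cells, with each expressed member as a grey line and the list median as a black line; red points stood above other genes, blue points below and white points within the random lists. The acinar median lay between -4.06 and -2.67 from day 1 to day 5 and at 0.20 on day 7.

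Signs of RNA quality and handling differed between libraries as well. The mRNAs of the mitochondrial genome stood below other genes on days 1, 5 and 7 (medians -0.98, -0.88 and -1.33) and within the random lists on days 3 and 4 (0.07 and 0.27). Ribosomal protein genes had medians of 0.04, 0.64, 0.35, -0.35 and -0.65 on days 1, 3, 4, 5 and 7, the first -0.29 at the lowest under another scaling. Immediate early and heat shock genes, which tissue dissociation also induces, stood below others on days 1 and 3 (medians -0.30 and -0.65) and above others on day 4 against day 3 (median 0.77). Xist, the X-inactivation RNA, was within 0.49 of mock in every library. The median log2 ratio of all expressed genes to mock was 0.15, 0.08, -0.01, 0.12 and -0.11 on days 1, 3, 4, 5 and 7, and -0.25 between days 7 and 5.

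Across the whole course 1465 genes, 14.7% of those expressed, had a range of 4-fold or more. The day 1 library held the highest value for 416 of them and the lowest for 463, day 3 for 325 and 264, day 4 for 167 and 232, day 5 for 118 and 187, day 7 for 308 and 296, and mock for 131 and 23. Day 7 held the highest value for 668 and the lowest for 72 with acinar, erythroid and mitochondrial genes left out. That setting also rescaled libraries to equal totals. Day 7 held the highest for 131 with genes that move with markers of other cells left out. Those genes were picked partly by their course over these same libraries, so a lower count was built in and decides nothing about other cells. Mock held the highest value for 222 without the day 3 library and for 263 without the day 7 library, and the lowest for 37 without day 7. Pearson correlations with mock across genes, which are not independent replicates, were 0.901, 0.921, 0.913, 0.915 and 0.937 on days 1, 3, 4, 5 and 7. The correlation between days 1 and 7 was 0.829, the lowest Pearson value of any pair, whereas by Spearman rho days 3 and 7 were lowest, at 0.829 against 0.833 for days 1 and 7.

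**Figure D4:**
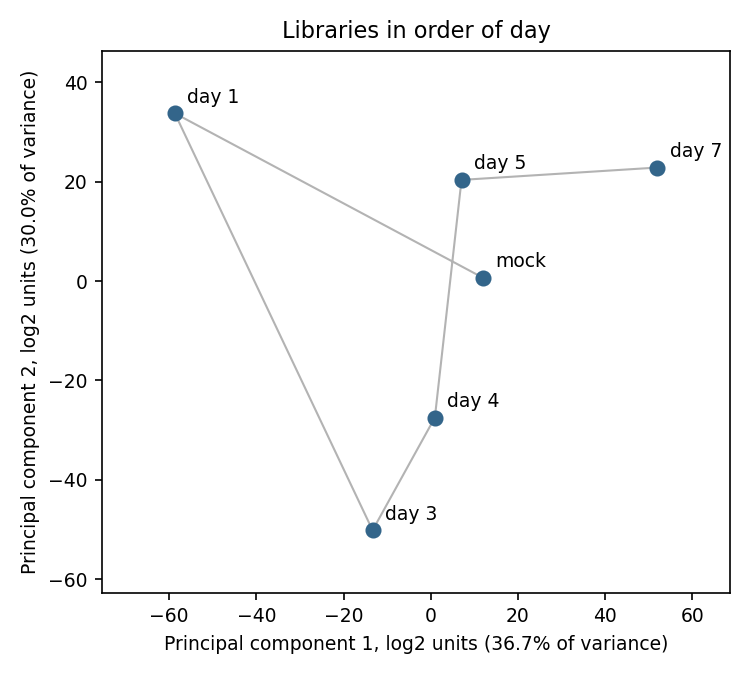
The 6 libraries on the first and second principal components of the gene-centred log2 values of 10000 genes, joined in order of day; the axes are in log2 units. The components held 36.7% and 30.0% of the variance, with day 1 at -58.7 and day 7 at 52.0 on the first and day 3 at -50.1 on the second.

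Of 35 lists with enough expressed members, 6, 6, 5, 5 and 8 stood above other genes on days 1, 3, 4, 5 and 7 against mock. On the same days 19, 15, 14, 20 and 11 stood below. Random lists, drawn gene by gene, would give 0.35 each way. Genes of a list can move together between any pair of libraries, and lists share members. The value for random lists is therefore no measure of variation between pools of mice. A count test that sets the 5 caerulein libraries against 1 mock library takes its spread from libraries of different days and cannot separate caerulein from that mock pool. It called 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 102 genes at an unadjusted p under 0.05. DESeq2 called 2, of which Ifnb1 was named after its values were seen: the fatty acid transporter gene Slc27a1 (log2 fold change 2.57, adjusted p = 0.00460, higher in all 5 caerulein libraries) and the interferon beta gene Ifnb1 (-4.37, adjusted p = 0.0457, lower in all 5). Ifnb1 had 232 reads in mock and 17, 15, 9, 10 and 2 on days 1, 3, 4, 5 and 7. The linear trend over day took mock as day 0, so its slope mixes the difference from mock with the course after caerulein. It cannot measure variation between pools of mice, since each day has 1 library. For this trend edgeR called 0 genes, with 806 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 19 lower with day. Lowest in adjusted p by DESeq2 among these was Irg1, which encodes the itaconate-producing enzyme, at -0.61 per day (adjusted p = 5.5e-07), and Clec4e was at -0.62 per day (adjusted p = 2.44e-06).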

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

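The tests of scaling, other cells, macrophage share, library preparation and thinned reads in this part were chosen after the results they bear on were seen, although the 3 other scalings themselves were fixed before. The values below are differences between the median log2 ratios to mock of a list on a pair of days, for lists that stood above other genes on 1 of the days and below on the other. With 1 library per day none of these differences was tested.

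Interferon-induced genes differed by 3.96 between days 1 and 3, being high on days 1 and 5 and low on days 3 and 4. Scaling is argued against, since the median between days 5 and 4 was at least 3.02 under 3 other scalings. More cells of another type stay open. Between days 5 and 4 the highest median of any list of other cells or monocytes, that of NK cell genes, was 1.70. It lay below the 25th percentile of the interferon-induced genes, 2.60, but the pseudocount understates ratios of low genes such as these. NK cell genes took 0.00369% of the reads on day 4 and 0.0204% on day 5, so that comparison does not decide the matter. For day 1 the monocyte median against mock was 1.72, above the 25th percentile of the interferon-induced genes on that day, 1.57. A difference between pools of mice or library preparations cannot be told apart from the day, because each day has 1 library, and the day after caerulein stays open as an untested biological explanation. RNA quality stays open too and was not tested. The mRNAs of the mitochondrial genome had medians of -0.98 and -0.88 on days 1 and 5 against 0.07 and 0.27 on days 3 and 4. Between days 5 and 4 they stood below others at -1.17, as did ribosomal protein genes at -0.57. On day 7, however, mitochondrial mRNAs had their lowest median, -1.33, while interferon-induced genes also stood below others, at -0.58. The opposite course of these lists did not hold on that day.

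Acinar genes differed by 4.26 between days 7 and 5, T cell genes by 3.01 and NK cell genes by 4.78 between days 7 and 3. A lower share of macrophages on day 7 that raises every other cell type alike is argued against as the whole cause. The medians of the other-cell lists between days 7 and 5 spanned 3.55, from 0.70 for endothelial and 0.84 for dendritic cell genes to 4.25 for acinar genes. The widest interquartile range within a list was 1.74. Part of the span can come from the pseudocount, which understates ratios of low genes, and from markers such as Kdr that were abundant without the rest of their list. Shares of reads, which have no pseudocount, also rose unequally. T cell genes took 0.0132% of the reads on day 5 and 0.0518% on day 7, and acinar genes 0.305% and 8.70%. A lower share as part of the cause stays open, since macrophage core genes were lower on day 7 than on day 5 in 12 of 17 cases (median -1.12, and -0.56 at the highest under another scaling). Scaling is argued against, since the lowest lymphocyte median was still 1.74 under 3 other scalings. More free acinar RNA or lymphocytes in the tissue by day 7, and the purity of each sort for CD45, CD11b and F4/80, which should remove both, stay open and were not tested.

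Cell-cycle genes differed by 3.86 between days 3 and 1. Scaling is argued against, since the median to mock was at least 1.35 under 3 other scalings. The larger number of reads on day 3 is argued against, since it would move genes of equal expression alike. Random lists matched on mean expression had a median of 0.06 on day 3 against mock. The cell-cycle median was 1.53. Its place at the 100th percentile of these lists is also how the list was flagged, so that place adds no separate support. With day 3 thinned to the smallest library the cell-cycle median was 1.52, but thinning keeps the expected ratio and so decides nothing. Dividing cells of another type cannot be told apart from dividing macrophages here, because 3 lists of other cells, those of duct, fibroblast and erythroid cells, also stood above other genes on day 3, the last not with quantile normalisation. RNA quality stays open and was not tested, with mitochondrial mRNAs at 0.96 and ribosomal protein genes at 0.60 between days 3 and 1. Between days 4 and 3, though, mitochondrial mRNAs were at 0.21 and ribosomal protein genes at -0.34, while cell-cycle genes were at -3.42. Mitochondrial mRNAs therefore did not follow the cell-cycle genes in that step. The day after caerulein, as the biological explanation, stays open too and was not tested.

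The other lists are given as values. Monocyte genes differed by 4.54 between days 1 and 5, and had a median of -0.35 between days 5 and 4. MHC class II genes differed by 2.90, alternative activation genes by 1.33 and dendritic cell genes by 1.49 between days 7 and 1. Matrix remodelling genes differed by 1.54 and unfolded protein genes by 1.80 between days 1 and 7. Growth factor genes differed by 1.20 and genes for uptake of dead cells by 0.63 between days 5 and 1. Ribosomal protein genes differed by 1.28 between days 3 and 7, duct cell genes by 3.80 and erythroid genes by 5.53 between days 3 and 5, fibroblast and stellate cell genes by 4.16 between days 3 and 1, and eosinophil genes by 2.49 between days 4 and 1.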

How the results depend on the processing

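Leaving out genes that move with markers of other cells, leaving out libraries, and the count tests were chosen after seeing the data. Of the alternative values, 360 of 445 counts stayed within 1.5 times, and 2601 of 2763 list results kept their standing. Direction was checked only for lists that stood above or below other genes in the report. Of the gene ratios, 432 of 743 lay within the counting interval of the report. That interval is for the ratio without pseudocount, and some ratios of the report already lay outside it. For Lipg on day 1 the ratio was 4.98 and the interval 5.77 to 8.14. The cause of the moves below was not tested, except that fewer or more genes enter with another filter. No paired analysis was possible because each day has 1 library. Depth limits the genes with few reads, such as Csf3 with 1 read on day 7, and the variation between pools of mice was not measured. Values in parentheses are those of the report.

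With a pseudocount 5 times as large, genes at least 2-fold higher numbered 234 on day 3 (373) and 74 on day 7 (196) against mock, and 636 on day 3 (972), 189 on day 4 (323), 345 on day 5 (540) and 334 on day 7 (507) against the preceding day. Lower were 601 on day 1 (958) and 432 on day 7 (657) against mock and 192 on day 5 against day 4 (311). A range of 4-fold was reached by 895 genes (1465). The highest value fell on mock for 70 (131), on day 3 for 191 (325), day 4 for 97 (167), day 5 for 75 (118) and day 7 for 153 (308), and the lowest on mock for 14 (23), day 1 for 244 (463), day 3 for 173 (264), day 4 for 149 (232), day 5 for 124 (187) and day 7 for 191 (296). Pearson correlations across genes with mock were 0.914, 0.932, 0.924 and 0.926 on days 1, 3, 4 and 5, and 0.844 between days 1 and 7.

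Among the 6000 highest genes, higher were 156 on day 3, 189 on day 4 and 58 on day 7 against mock, and 382 on day 3, 157 on day 4 and 159 on day 7 against the preceding day. Lower were 364, 298, 395 and 268 on days 1, 3, 4 and 5 against mock, and 542, 276 and 169 on days 3, 4 and 5 against the preceding day. A range of 4-fold was reached by 773. The highest value fell on mock for 60, day 3 for 140, day 4 for 92 and day 7 for 86, and the lowest on mock for 11, day 1 for 173, day 3 for 145, day 4 for 121 and day 5 for 88. Correlations with mock were 0.853, 0.886, 0.872, 0.869 and 0.909 on days 1, 3, 4, 5 and 7, and 0.742 between days 1 and 7. Lists above other genes numbered 3 on day 4 (5) and 4 on day 7 (8). The median of resident macrophage genes turned to -0.014 between days 7 and 5 (0.05), and that of alternative activation genes to -0.12 on day 7 (0.21).

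With no filter, higher were 415 on day 7 against mock, and 1570 on day 3 and 1149 on day 7 against the preceding day. Lower were 1509 on day 1 and 1049 on day 5 against mock, and 941 on day 4 and 469 on day 5 against the preceding day. The highest value fell on day 7 for 492. Lists above other genes numbered 3 between days 5 and 4 (6). Duct cell genes turned to -0.27 on day 1 (0.71).

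After centring on the median gene, 475 genes were lower on day 5 than on day 4, 263 were lower on day 7 than on day 5 (468), and the lowest value fell on day 7 for 176. With quantile normalisation 438 were higher on day 7 than in mock, the lowest value fell on mock for 62, and 3 lists stood above on day 5 (5). With acinar, erythroid and mitochondrial genes left out, higher than mock were 320, 247, 170, 187 and 686 on days 1, 3, 4, 5 and 7, and 1040 were higher on day 7 than on day 5. Lower were 260 on day 7 against mock and 119 against day 5. The highest value fell on day 1 for 266 (416), day 4 for 99 and day 7 for 668, and the lowest on day 7 for 72. That setting also rescaled libraries to equal totals, and neither step was run alone. It moved the median of all expressed genes to mock to -0.17, -0.10, -0.28, -0.11 and 0.20 on days 1, 3, 4, 5 and 7. The median of alternative activation genes between days 7 and 5 (-0.01) turned to 0.14 with no filter, 0.20 after centring, 0.43 with quantile normalisation, 0.54 with those genes left out and 0.29 as a mean.

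As means in place of medians, 3 lists stood above on day 4, 3 on day 5 and 8 between days 3 and 1 (13). The mean of alternative activation genes on day 7 was -0.48 and that of glycolysis genes between days 7 and 5 was -0.0082 (0.02). With genes that move with markers of other cells left out, 250 were higher on day 7 than on day 5, 357 were lower on day 3 than in mock, the highest value fell on day 7 for 131 and the lowest on day 3 for 163. Those genes were picked partly by their course over these same libraries, so lower counts were built in. Without the day 3 library the highest value fell on mock for 222 genes. Without the day 7 library it fell on mock for 263, and the lowest for 37. Leaving out mock moved none of these counts past 1.5 times. DESeq2 called 2 genes for caerulein against mock and 20 for the trend, where edgeR called 0 and 0. A pseudocount of 1.78 and random lists not matched on expression moved no count past 1.5 times.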

Other observations

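The following genes were chosen after their values were seen, belong together by no fixed list and were not tested as a group. Tmem119 had a normalised read count of 636 in mock and of 633, 2097, 888, 2967 and 1101 on days 1, 3, 4, 5 and 7. Gpr34 had 1293 in mock and 62.8, 2390, 5647, 3377 and 1626 on those days. Ms4a7 had 4292 in mock and 17973, 19486, 40439, 43214 and 8671.

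The mitochondrial leucyl-tRNA synthetase gene Lars2 had a normalised read count of 13854 in mock, 15459 on day 1, 420 on day 3, 23516 on day 4, 7232 on day 5 and 3952 on day 7. The predicted gene Gm15564, also chosen after its values were seen, had 90.7 in mock and 78.8, 16.2, 182, 49.9 and 37.2 on days 1, 3, 4, 5 and 7.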
